A study of Drosophila melanogaster with 18 samples.

How the data were processed

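RNA was measured in 18 samples of Kc cells, a Drosophila melanogaster line of embryonic origin, on NimbleGen expression arrays with 1 colour (Cy3). Cells had received double-stranded RNA daily for 3 days and were collected on day 4, per the labels' protocols. The values are log2 signals for each transcript that the authors deposited as 1 table. RMA and Partek are named in the submitters' processing notes, and their versions are not given in the sources used here. RMA in general corrects background, equalises the intensity distributions of the arrays it is run on and summarises probes into 1 log2 value. Whether all 18 arrays were run through it together is not given in the sources used here. The table holds 16637 rows, each a FlyBase transcript identifier, and every value column was matched to 1 sample by its name. It carries no detection call or background measure, so a low value cannot be separated from background, and the number of arrays, 2 per group, limits the precision.

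Samples were grouped by the labels into control (double-stranded RNA against beta-galactosidase), 4 single knockdowns (BEAF, CP190, CTCF and SuHw) and 4 double knockdowns (BEAF+CP190, BEAF+CTCF, CTCF+CP190 and SuHw+CP190), with 2 arrays in each of the 9 groups. The design text in the labels calls the 2 arrays of a group biological replicates from independent experiments. Control, BEAF and CP190 samples have the cell line written in a different way from the other 6 groups, and the arrays divide along the same line. These are called the first set (6 arrays) and the second set (12 arrays). What the wording stands for is not given in the sources used here.

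The deposited log2 values were used with no further normalization or filter. A mean per group was fitted over all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups shared an estimate of each transcript's spread, with 9 residual and 3.68 prior degrees of freedom. A transcript was called when its two-sided p, adjusted by Benjamini-Hochberg over all transcripts of a comparison, was under 0.05. The 20 comparisons were each knockdown against control, each double knockdown against both of its singles, and the interaction of each pair, which is the double minus both singles plus control. Fold changes are differences of mean log2 signals, and where the lower signal lies near the low end they need not equal the fold of the RNA. On simulated arrays with known changes, BEAF against control recovered 77% of the transcripts changed by 0.5 on the log2 scale and 99% of those changed by 1, with 9 calls among unchanged transcripts. The BEAF+CTCF interaction recovered 48% and 93%, with 8 calls among unchanged transcripts.

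Correlations between comparisons were taken across transcripts, which are not independent replicates. For each, unchanged groups on the same arrays were simulated (20 draws), and the overlap of calls was set beside the overlap that independent lists would have. The ± of a correlation is its SD over choices of a single replicate array for the first-named group of each comparison. All other groups, control included, stayed as means of their arrays. The SD therefore leaves out their spread and is not the full error of the correlation. Transcripts were also counted as set apart by a protein within the second set when every array with that knockdown lay at least 2-fold above, or at least 2-fold below, every array without it. This count uses no control array and was added after the data were examined. In simulated arrays whose groups did not differ otherwise, it found 0 unchanged transcripts for each protein. Of 200 changed by 2 on the log2 scale it found 199 for CTCF, with 6 arrays against 6. It found all 200 for CP190 (6 against 6) and for BEAF and SuHw (4 against 8). The simulation left out other differences between groups, so it gives no rate of false finds in the real arrays.

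Names came from the synonyms of the given RefSeq gene table (17872 genes, Release 6 assembly). They matched 16 transcripts to 1 symbol, 28 to several and 16593 to none. Of the 16, 2 have only an annotation number, which leaves 14 named genes. None of the 4 targeted genes was among them, so the levels of the targets were not analysed here. The 27 gene lists fixed before the data were examined and the comparison of neighbouring genes were not run for the same reason. The rule for named genes, fixed before the data were examined, took per single knockdown up to 10 rises and 10 falls, and per double knockdown or interaction up to 5 each way. It took the largest changes past the threshold, and against control required both knockdown arrays to lie on the same side of both control arrays. Where fewer than 3 passed, the 3 with the smallest p are given as values. Other transcripts appear by identifier, up to 2 each way in a comparison, and these were chosen for their size after their values were seen.

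Alternatives fixed before the data were examined were a fit of only the groups compared, the replicate number as a block, only transcripts above the median signal, quantile normalization of the 18 arrays, and leaving out each array in turn. Where that leaves 1 array in a group, its spread is assumed to be like that of the other groups. Alternatives added afterwards were a fit of only the arrays of the same set, a gap of 1.5-fold, correlations with each of 2 shared arrays given to a different comparison, and an additive model of the 4 knockdowns within the second set. In that model each protein's effect is fitted with the other knockdowns held fixed, and is not the plain difference between second-set arrays with and without it. Every second-set group but BEAF+CP190 has CTCF or SuHw knocked down. The level without either therefore rests on the BEAF+CP190 arrays and on BEAF and CP190 effects that add.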

Results

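The series measured transcript levels in Kc cells, a Drosophila line of embryonic origin, after RNA interference against proteins of chromatin insulators. BEAF, CTCF and SuHw bind DNA directly, and CP190 is a cofactor found with each of them. The 18 arrays comprised 9 groups of 2 independent experiments: control cells given double-stranded RNA against beta-galactosidase, 4 single knockdowns (BEAF, CP190, CTCF, SuHw) and 4 double knockdowns (BEAF+CP190, BEAF+CTCF, CTCF+CP190, SuHw+CP190). Values were log2 RMA signals of 16637 transcripts. Folds are ratios of signal, and where the lower signal is near the low end, as for FBtr0077686, FBtr0085456 and FBtr0078763, it cannot be separated from background and the fold of the RNA may be larger. The identifiers of all but 14 named genes were not paired with names here, and the targeted genes were not analysed here.

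Replicate arrays correlated across transcripts at 0.9981 to 0.9994, above any pair of arrays from different groups of the first set (0.9924 to 0.9977). Groups of the second set correlated at 0.9895 to 0.9982, and arrays of different sets at 0.9777 to 0.9897. The root mean square SD between replicates ran from 0.0813 for CTCF to 0.148 for SuHw on the log2 scale (n = 2 each). The first principal component took 56.1% of the variance and separated control, BEAF and CP190 arrays from the other 6 groups, which are also the groups whose cell line is written differently in the labels. Each group lies in 1 set, so for any comparison across the sets the set and the knockdown cannot be told apart. A constant difference between the sets cancels in BEAF and CP190 against control and in the doubles against CTCF or SuHw. It also cancels in the interactions of BEAF+CTCF, CTCF+CP190 and SuHw+CP190. Those interactions set an effect measured in the second set against 1 measured in the first. A knockdown effect that differs by set cannot be told apart from an interaction there.

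**Figure D1:**
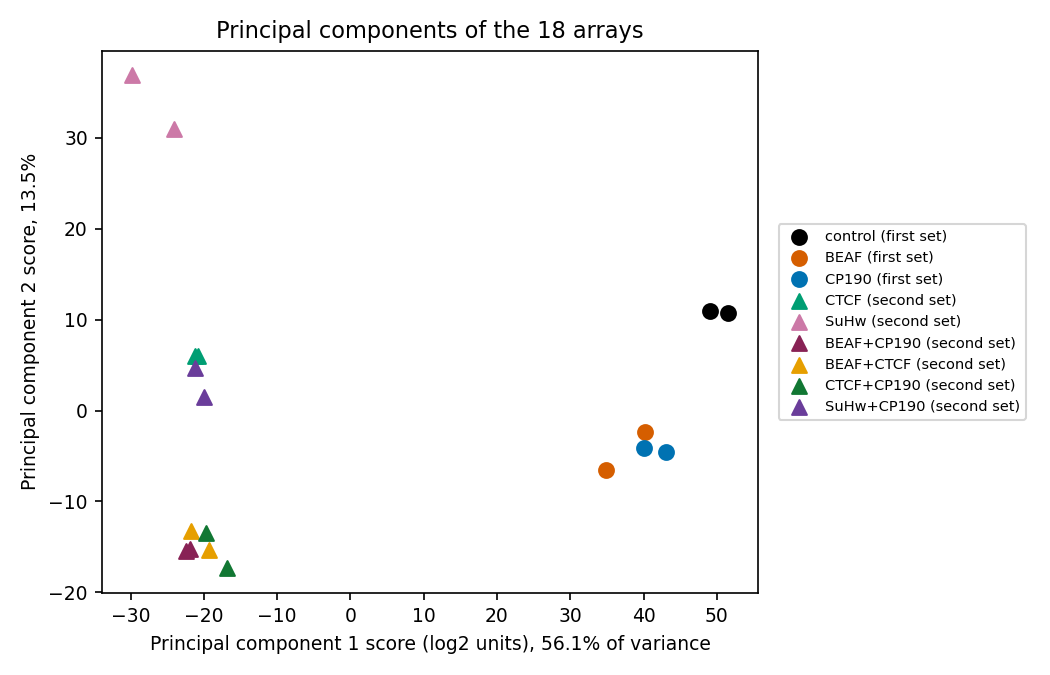
Scores of the 18 arrays on the first and second principal components of the log2 signals (56.1% and 13.5% of the variance), each point 1 array, circles for the first set and triangles for the second. The 6 arrays of control, BEAF and CP190 lie to the right of the 12 arrays of the other groups.

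After knockdown of BEAF, more transcripts fell than rose by at least 2-fold, as after every knockdown compared with the same 2 control arrays. Doubles against CTCF or SuHw, which use no control array, had no such steady excess. There 62 rose and 75 fell for BEAF+CTCF, 102 and 66 for CTCF+CP190, and 141 and 125 for SuHw+CP190. Whether the control arrays or the knockdown gave the excess cannot be told apart. In BEAF against control, 298 fell and 44 rose by that much, among 3334 that fell and 3609 that rose at any size. Above the median signal 70 fell and 20 rose by at least 2-fold. The transcript FBtr0087442 went from a log2 signal of 9.05 ± 0.098 in control to 11.71 ± 0.18 (SD, n = 2 each), a 6.29-fold rise (limma with Benjamini-Hochberg, adjusted p = 8.3e-09), and FBtr0083330 fell by 2.56 on the log2 scale (SE 0.092, adjusted p = 8.3e-09). Of the 14 named genes, 4 rose, 3 fell and 7 did not pass. The chromatin remodeller gene kis rose by 0.47 (SE 0.06, adjusted p = 6.3e-05) and sle, which encodes a nucleolar protein, by 0.32 (SE 0.057). The gene fend fell by 0.68 (SE 0.074, adjusted p = 1.6e-05) and the phosphate transporter gene NaPi-III fell by 0.55 (SE 0.054) on the log2 scale. The laminin gene LanA (0.17), the ubiquitin-activating enzyme gene Uba1 (0.15) and the fatty acid transporter gene Fatp1 (-0.22) passed narrowly and lost their calls without BEAF replicate 1, at 0.13, 0.17 and -0.20, as well as without other single arrays. Without BEAF replicate 1 the total of 6943 called transcripts was 4316, and the balance at any size turned to 2021 that rose and 2295 that fell. It turned to 2260 and 2523 without control replicate 1 and to 2495 and 2589 without control replicate 2. Without BEAF replicate 2, 79 rose and 435 fell by at least 2-fold.

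Knockdown of CP190 gave 214 transcripts lower and 34 higher by at least 2-fold than the same 2 control arrays. These were among 3229 that fell and 2587 that rose. At any size this balance turned to 2901 that fell and 3110 that rose with quantile normalization, and to 1542 and 2118 above the median signal, while by at least 2-fold 159 fell and 42 rose, and 29 fell and 18 rose. Without control replicate 1, 1561 rose and 2390 fell at any size, and without control replicate 2, 1628 and 2332. FBtr0078763 rose from a log2 signal of 5.20 ± 0.15 in control to 7.29 ± 0.20 (SD, n = 2 each), a 4.25-fold rise (limma with Benjamini-Hochberg, adjusted p = 1.9e-07), and FBtr0089746 fell by 2.66 on the log2 scale (SE 0.088, adjusted p = 3.5e-09). Among the named genes, 3 rose, 4 fell and 7 did not pass. As after BEAF knockdown, kis rose by 0.31 (SE 0.06, adjusted p = 0.0015) and sle by 0.28 (SE 0.057), and fend fell by 1.13 (SE 0.074, adjusted p = 6.8e-07) and NaPi-III fell by 0.34 (SE 0.054). Wdr24, which encodes a subunit of the GATOR2 complex, the Hedgehog pathway gene rdx and Fatp1 passed at 0.26, -0.35 and -0.19. These 3 lost their calls without CP190 replicate 1, at 0.22, -0.34 and -0.15, and without other single arrays.

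The changes after BEAF and after CP190 knockdown resembled each other. Across transcripts their log2 changes against control correlated at 0.794 ± 0.025 (SD over replicate choices), where unchanged groups sharing the same 2 control arrays gave 0.5 in simulation. The covariance was 0.0944 against a simulated 0.00512. Both knockdowns called 4279 transcripts in the same direction, where independent lists would share 1208, and 83 in opposite directions. With a different control array for each knockdown, so that no array was shared, they correlated at 0.726 or 0.757, with covariances of 0.0897 and 0.092, depending on which array went with which. Part of the excess of shared calls may come from the shared control arrays.

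Knockdown of SuHw set 45 transcripts apart as higher and 1 as lower within the second set. In the 45, all 4 arrays with SuHw knockdown, alone or with CP190, lay at least 2-fold above all 8 arrays without it. Their median rise was 4.47-fold, 30 rose at least 4-fold, and 13 lay below the lower quartile of all signals without the knockdown. FBtr0077686 had a log2 signal of 10.76 ± 0.096 with the knockdown (SD, n = 4) and 5.19 ± 0.65 without (SD, n = 8), a 47.4-fold higher signal, and FBtr0088597 11.35 ± 0.13 and 6.84 ± 0.25, a 22.8-fold higher signal. The transcript that was lower, FBtr0086519, had 9.32 ± 0.41 and 11.23 ± 0.35. Of the 45, 31 also lay at least 2-fold above all 6 arrays of the first set. A smaller gap of 1.5-fold gave 74 higher and 5 lower.

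In SuHw+CP190 against SuHw, 8 of the 45 were higher, 19 lower and 18 not called, with a median log2 difference of -0.19 and a range of -0.79 to 1.17. The choice of the 45 required the gap in the double too, so whether a rise was lost there cannot be read from them.

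Knockdown of CTCF set 10 transcripts apart as higher and 5 as lower, comparing its 6 second-set arrays with the other 6. The median rise was 4.76-fold, and 8 of the 10 rose at least 4-fold. FBtr0085456 had a log2 signal of 9.69 ± 0.15 with the knockdown and 4.98 ± 0.16 without (SD, n = 6 each), a 26.2-fold higher signal, and FBtr0100534 8.24 ± 1.00 and 4.18 ± 0.22. Lower were FBtr0081748, at 5.77 ± 0.093 and 8.02 ± 1.00, and FBtr0114532, at 8.91 ± 0.21 and 10.71 ± 0.12. Against all 6 arrays of the first set, 8 of the 10 and 4 of the 5 kept the 2-fold gap. When CP190 was depleted together with CTCF, 9 of the 10 raised transcripts were lower than with CTCF alone and 1 was not called, with a median log2 difference of -0.48. When BEAF was depleted with CTCF, 2 were higher, 2 lower and 6 not called. The choice required the gap in both doubles, and the difference between the doubles in these 10 was not tested.

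Knockdown of BEAF set 9 transcripts apart as lower and 2 as higher within the second set, comparing 4 arrays with 8, and 28 and 6 with a gap of 1.5-fold. FBtr0074827 had a log2 signal of 5.89 ± 0.20 with the knockdown (SD, n = 4) and 8.36 ± 0.074 without (SD, n = 8), and FBtr0087441 8.96 ± 0.12 and 11.37 ± 0.076. FBtr0087442 was higher, at 11.78 ± 0.059 and 9.93 ± 0.08, and FBtr0085063 at 6.84 ± 0.20 and 5.29 ± 0.25. In the first set, whose arrays took no part in that choice, all 9 also fell and both others rose in BEAF against control. The shares of all transcripts called in those directions would give 1.8 and 0.434. Transcripts of the targeted genes were not identified and may be among those set apart as lower, here and for the other proteins.

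Knockdown of CP190 set 10 transcripts apart as higher and 3 as lower, 6 second-set arrays against 6, and 37 and 19 with a gap of 1.5-fold. FBtr0078763 had a log2 signal of 8.90 ± 0.45 with the knockdown and 5.29 ± 0.31 without (SD, n = 6 each), a 12.2-fold higher signal, and FBtr0080239 8.35 ± 0.20 and 5.11 ± 0.38. FBtr0081085 was lower, at 8.15 ± 0.14 and 9.89 ± 0.35. Among first-set arrays FBtr0080239 was at 7.05 ± 0.064 in control, 8.14 ± 0.094 in CP190 and 5.88 ± 0.041 in BEAF. Its second-set level of 5.11 without CP190 knockdown thus lay below control, across the sets. In the first set, 7 of the 10 rose in CP190 against control, 2 fell, and 1 of the 3 fell, where 1.55 and 0.582 were the numbers given by the shares of all transcripts. Against BEAF in place of control, 8 of the 10 were higher and all 3 lower in CP190 arrays. Without replicate 1 of every group the total of 13 was 20, since fewer arrays have to be passed.

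**Figure D2:**
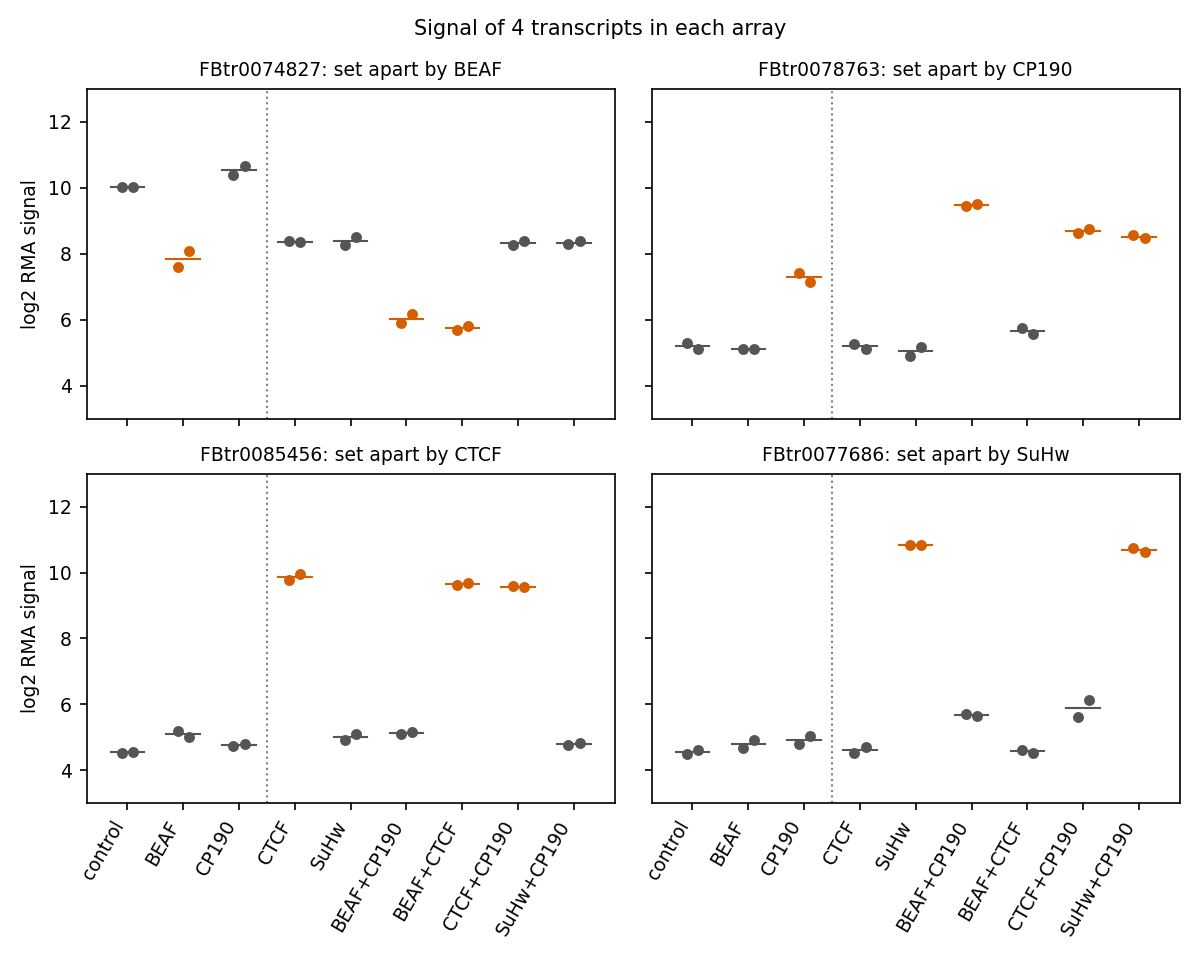
The log2 RMA signal of 4 transcripts in each of the 18 arrays (points, with a line at the mean of each group of 2), orange where the named protein was knocked down, and a dotted line between the first set on the left and the second on the right. For each protein the transcript with the largest fold of signal among those set apart within the second set is drawn. FBtr0077686 lies between 10.63 and 10.84 in the 4 SuHw arrays and between 4.54 and 6.13 in the other 8 of the second set.

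CTCF and SuHw against control compare arrays of different sets. For CTCF, 4847 transcripts were higher and 4286 lower than in control, 474 and 875 of them by at least 2-fold. For SuHw, 4930 were higher and 4839 lower, 641 and 968 by at least 2-fold. For SuHw the balance at any size turned without SuHw replicate 2 (4168 and 4279), without control replicate 1 (4100 and 4110) and with only these groups in the fit (4049 and 4170). In CTCF arrays kis was higher by 0.98 (SE 0.06), alpha-Spec, the gene of a spectrin chain, by 0.32 and sle by 0.29, while fend was at -1.68 (SE 0.074), Fatp1 at -0.55 and mio, another GATOR2 gene, at -0.24. In SuHw arrays kis was higher by 0.73, NaPi-III by 0.37 and sle by 0.34, while fend was at -1.95 (SE 0.074, limma with Benjamini-Hochberg, adjusted p = 2e-10), Fatp1 at -0.76 and mio at -0.29. In CTCF arrays His4r, a histone H4 gene, HDAC3 and NaPi-III passed at 0.21, 0.17 and 0.16, and without CTCF replicate 2 they did not, at 0.17, 0.12 and 0.15. Without control replicate 1 His4r was at 0.14 there. In SuHw arrays rdx and His4r passed at 0.33 and 0.28, and without SuHw replicate 2 they did not, at 0.16 each. In the additive model within the second set, 1446 transcripts were called for CTCF (634 higher and 812 lower), 299 of them in the direction found against control and 725 in the opposite one. For SuHw it called 820, 275 in that direction and 366 in the opposite one, with 114 higher and 35 lower by at least 2-fold. Only the BEAF+CP190 arrays of that set have neither knockdown. These counts therefore assume that BEAF and CP190 effects add, and do not by themselves show that a change reverses. None of these named genes kept its call in that model. His4r was not called but stayed at 0.25 for CTCF and 0.26 for SuHw, mio at -0.16 and -0.20 and HDAC3 for CTCF at 0.10, while kis turned to -0.087 for CTCF and -0.21 for SuHw and fend to 0.28 and 0.15.

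The double knockdowns against control also cross the sets and gave lists of similar length. BEAF+CP190 had 4994 transcripts higher and 4312 lower, BEAF+CTCF 4881 and 4249, CTCF+CP190 4552 and 4128, and SuHw+CP190 4541 and 4309. By at least 2-fold, 602, 534, 459 and 539 were higher and 880, 930, 856 and 847 lower. FBtr0088865 was higher than in control by 5.45 to 6.37 on the log2 scale in all 6 groups of the second set, whatever the protein. FBtr0075682 was among the lowest in SuHw and all 4 doubles, at -4.99 to -5.33. It was low in CTCF arrays too, with a mean log2 signal of 6.48 against 11.62 in control. His4r was higher in each double, by 0.69, 0.62, 0.59 and 0.54 (SE 0.077), and kis by 0.81, 0.83, 0.75 and 0.74 (SE 0.06). Levels of fend were lower, at -1.18, -1.07, -1.65 and -1.65 (SE 0.074), those of Fatp1 at -0.39, -0.53, -0.37 and -0.45, and those of mio at -0.29, -0.32, -0.38 and -0.41.

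Smaller differences of named genes against control varied between the doubles. In BEAF+CP190, BEAF+CTCF and CTCF+CP190 arrays alpha-Spec was higher by 0.29, 0.24 and 0.30 and sle by 0.19, 0.26 and 0.16, and in SuHw+CP190 arrays alpha-Spec by 0.26. SuUR, a gene of heterochromatin replication, was at -0.24, -0.20, -0.25 and -0.18 in the 4 doubles. NaPi-III in BEAF+CP190 (-0.16), HDAC3 in BEAF+CTCF (0.19) and Wdr24 in SuHw+CP190 (-0.19) also passed. Without replicate 1 of the double, SuUR lost its call in each (-0.23, -0.16, -0.20 and -0.18), as did NaPi-III (-0.17), HDAC3 (0.20) and Wdr24 (-0.16), while sle lost its call without replicate 2 of BEAF+CP190 (0.17) and of CTCF+CP190 (0.12). In the additive model within the second set 5268, 2537, 3563 and 2702 transcripts were called, of which 2344, 1288, 1464 and 1208 had the direction found against control and 1297, 546, 917 and 674 the opposite one. By at least 2-fold it had 484, 382, 428 and 432 higher and 458, 487, 517 and 417 lower. The model again assumes that BEAF and CP190 effects add. In that model kis turned to between -0.17 and -0.32 and fend to between 0.32 and 0.96, and only His4r in the 4 doubles and NaPi-III in BEAF+CP190 kept their calls among these named genes. Of those not called, mio stayed at -0.20, -0.23, -0.29 and -0.32, SuUR at -0.19, -0.15, -0.19 and -0.15, HDAC3 in BEAF+CTCF at 0.14 and Wdr24 in SuHw+CP190 at -0.14.

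**Figure D3:**
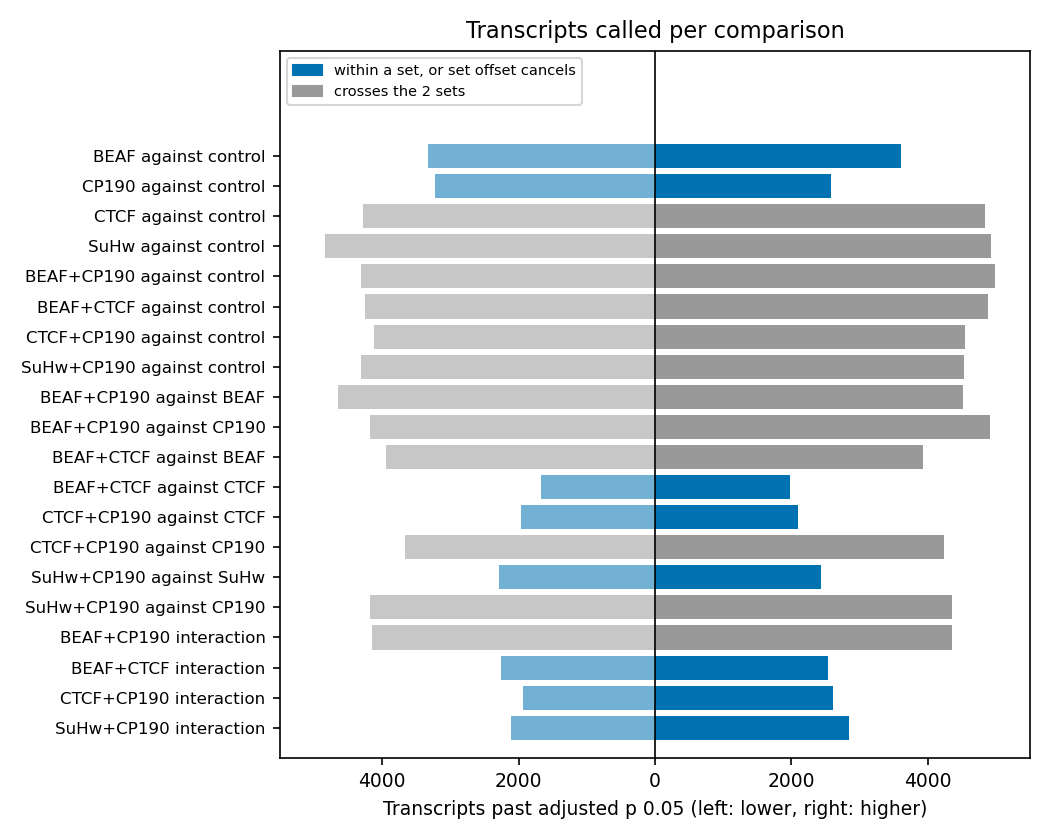
Number of transcripts past an adjusted p of 0.05 in each of the 20 comparisons, higher to the right and lower to the left. Blue marks comparisons in which a constant difference between the sets cancels, and grey those that cross the sets. The 8 blue bars hold 3642 to 6943 transcripts in all and the 12 grey bars 7877 to 9769.

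Adding a BEAF knockdown to CTCF raised 1976 transcripts and lowered 1666, 62 and 75 of them by at least 2-fold. Above the median signal 1186 rose and 1137 fell, 6 and 29 by at least 2-fold. FBtr0087442 rose 3.76-fold and FBtr0087441 fell by 2.51 on the log2 scale (SE 0.057, limma with Benjamini-Hochberg, adjusted p = 5.1e-11). His4r rose by 0.40 (SE 0.077) and fend by 0.62 (SE 0.074), NaPi-III fell by 0.23, and the other 11 named genes did not pass. Leaving out any 1 of the 4 arrays reduced the total of 3642 to between 2016 and 2099, and without BEAF+CTCF replicate 1, at 2062, NaPi-III was not called (-0.23).

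Adding a CP190 knockdown to CTCF raised 2096 transcripts and lowered 1969, 102 and 66 by at least 2-fold. FBtr0078763 rose 11.4-fold and FBtr0080239 10.4-fold, and FBtr0100534 fell by 2.05 on the log2 scale (SE 0.14, limma with Benjamini-Hochberg, adjusted p = 8.6e-07). His4r rose by 0.38 (SE 0.077), NaPi-III and kis each fell by 0.23, and 11 named genes did not pass. The total of 4065 was 2325 without CTCF+CP190 replicate 1, where NaPi-III (-0.18) and kis (-0.22) were not called, 2354 without CTCF replicate 1 and 2364 without CTCF replicate 2. Without CTCF+CP190 replicate 2 the balance turned, with 1534 that rose and 1590 that fell, 100 and 111 by at least 2-fold. Above the median signal 1356 rose and 1394 fell, 19 and 11 by at least 2-fold.

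Adding a CP190 knockdown to SuHw raised 2437 transcripts and lowered 2284, 141 and 125 by at least 2-fold. The same FBtr0078763 and FBtr0080239 rose 11.2-fold and 10.9-fold, and FBtr0113150 fell by 3.02 on the log2 scale (SE 0.10, limma with Benjamini-Hochberg, adjusted p = 2.7e-09). Fatp1 rose by 0.32, fend by 0.31 and His4r by 0.26, NaPi-III fell by 0.35 and sle fell by 0.20, and 9 named genes did not pass. The balance turned with quantile normalization, to 2352 that rose and 2456 that fell (134 and 147 by at least 2-fold), and without SuHw replicate 1, to 2440 and 2655 (150 and 217). Above the median signal 1462 rose and 1532 fell, 35 and 19 by at least 2-fold. With only the SuHw and SuHw+CP190 arrays in the fit, the total of 4721 was 1831 and none of these 5 genes passed. Without SuHw+CP190 replicate 2 it was 3130, and His4r (0.23) and sle (-0.15) were not called.

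The doubles against BEAF or CP190 alone cross the sets. BEAF+CP190 differed from BEAF in 9161 transcripts and from CP190 in 9102, BEAF+CTCF from BEAF in 7877, CTCF+CP190 from CP190 in 7906 and SuHw+CP190 from CP190 in 8545. In all 5, FBtr0088865 was the transcript with the largest rise, by 5.83 to 6.76 on the log2 scale, and FBtr0075682 that with the largest fall, at -4.59 to -4.89.

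Adding a CP190 knockdown changed transcripts alike on the CTCF and SuHw backgrounds. A response to a second double-stranded RNA, whatever its target, could contribute to this, and the design has no control with 2 of them. Across transcripts the log2 changes of CTCF+CP190 against CTCF and of SuHw+CP190 against SuHw, which share no array, correlated at 0.742 ± 0.032 (SD over replicate choices), with 2595 transcripts called in the same direction against 577.3 for independent lists and 40 in opposite directions against 576.2, and unchanged groups simulated on these arrays gave 0.00346. BEAF on CTCF and CP190 on SuHw, again with no shared array, correlated at 0.435 ± 0.031 (0.0018 simulated), with 1670 in the same direction and 198 in opposite ones, against 518.2 and 515.3 for independent lists. BEAF and CP190 on the same CTCF arrays correlated at 0.593 ± 0.026, beside 0.5 for unchanged groups sharing 2 arrays, with a covariance of 0.0462 beside a simulated 0.00511. With a different CTCF array for each they correlated at 0.529.

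The effects measured against control carried over less to these backgrounds. Those effects come from the first set and the ones on the backgrounds from the second, so background and set cannot be told apart. BEAF against control and BEAF+CTCF against CTCF correlated at 0.194 ± 0.034 across transcripts (-0.00118 simulated), with 1372 called in the same direction and 632 in opposite ones, against 762.5 and 757.4 for independent lists. CP190 against control correlated at 0.147 ± 0.047 with CP190 on CTCF (-0.00168 simulated), with 1196 in the same direction and 800 in opposite ones against 708.1 and 713. With CP190 on SuHw it correlated at 0.139 ± 0.02 (-0.00245 simulated), with 1239 and 961 against 822.2 and 828.1. Among transcripts above the median signal the BEAF correlation was 0.343, and those of CP190 were at most 0.163. The difference between BEAF and CP190 arrays of the first set, which uses no control, correlated at 0.59 ± 0.031 with the difference between BEAF+CTCF and CTCF+CP190 arrays of the second (0.000424 simulated). Here 824 transcripts were called in the same direction and 14 in opposite ones, against 109.9 and 110.6 for independent lists.

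**Figure D4:**
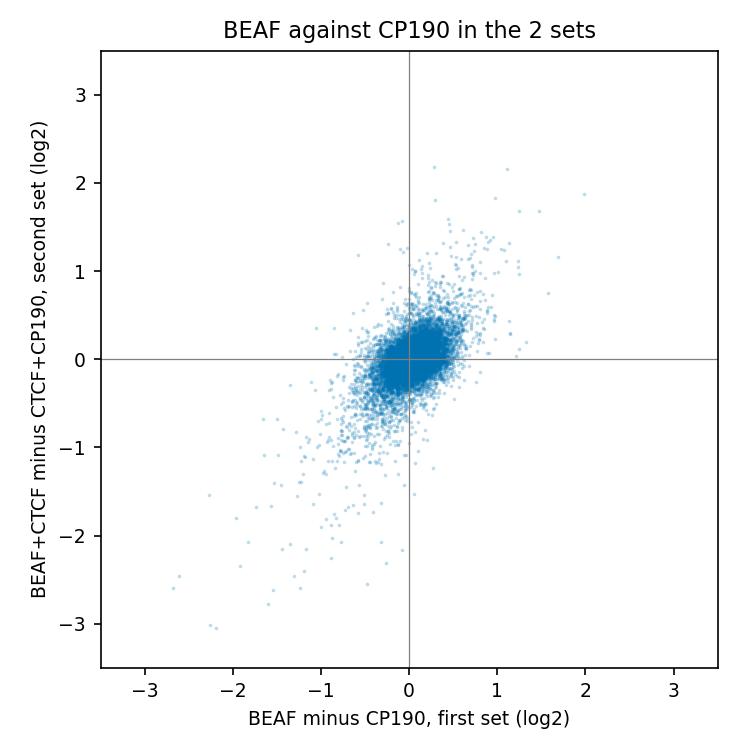
Each point is 1 of 16637 transcripts, with the log2 difference BEAF minus CP190 in the first set on the horizontal axis and BEAF+CTCF minus CTCF+CP190 in the second set on the vertical axis. The points follow the diagonal, with a correlation of 0.59 across transcripts.

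Among the knockdowns against control, CTCF and SuHw correlated at 0.871 ± 0.009, beside 0.498 for unchanged groups sharing the control arrays. The covariance was 0.362 beside a simulated 0.00505. Both comparisons cross the sets, and the simulated values leave out the difference between the sets, which enters both. All 15 pairs of knockdowns of the second set lay between 0.785 and 0.947, and the 12 pairs with 1 knockdown in each set between 0.379 and 0.618.

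Interactions asked whether a double knockdown differed from the sum of its singles. For BEAF+CTCF, 2534 transcripts lay above the sum and 2262 below, for CTCF+CP190 2616 and 1935, and for SuHw+CP190 2841 and 2114. At any size this balance depended on the setting. It was 2452 and 2526, 2398 and 2369, and 2466 and 2516 with quantile normalization, and 1283 and 1665, 1289 and 1710, and 1382 and 1793 above the median signal. Leaving out some single arrays widened it. For BEAF+CTCF, 1922 lay above and 1325 below without BEAF+CTCF replicate 2, 1928 and 1356 without BEAF replicate 1, 1936 and 1439 without CTCF replicate 1, 1948 and 1392 without CTCF replicate 2, and 1950 and 1382 without control replicate 1. For CTCF+CP190, 2073 lay above and 1217 below without CTCF replicate 1, 2096 and 1252 without CTCF replicate 2, and 2085 and 1233 without control replicate 1. For SuHw+CP190, 2147 lay above and 1250 below with only the groups compared in the fit. By at least 2-fold, 448, 495 and 549 lay above and 64, 56 and 99 below, and with quantile normalization 381, 369 and 403 above and 102, 89 and 156 below. Without SuHw replicate 1, 543 lay above and 162 below for SuHw+CP190. These interactions all include the same control arrays, and those with CP190 the same CP190 arrays, so they are not independent. Control enters them with a plus sign, so a transcript lower by a similar amount in every knockdown lies above the sum. The excess above the sum by at least 2-fold may thus mirror the excess of falls against control. A response to a second double-stranded RNA in the doubles, whatever its target, could enter the interactions too. Mean log2 signals of fend were 10.47 in control and 8.52 to 9.79 in the other groups. An effect of BEAF or CP190 that differs between the sets would also enter them. The fend transcript lay above the sum by 1.30, 1.16 and 1.43 (SE 0.10 each), with adjusted p of 5.6e-06, 9.5e-06 and 1.2e-06 by limma with Benjamini-Hochberg, and His4r by 0.54, 0.57 and 0.45 (SE 0.11). Levels of sle lay below it, at -0.35, -0.42 and -0.48 (SE 0.08), and those of kis at -0.62, -0.54 and -0.31 (SE 0.085). Only these last 2 genes were called below the sum in CTCF+CP190, where Uba1 at -0.18, mio at -0.21 and Wdr24 at -0.23 did not pass (adjusted p of 0.06, 0.09 and 0.1 by limma with Benjamini-Hochberg). With only the groups compared in the fit, His4r (0.45) and kis (-0.31) were not called in SuHw+CP190, and kis was not called there without SuHw+CP190 replicate 2 (-0.26). In BEAF+CP190, which crosses the sets, 4361 transcripts lay above the sum and 4150 below, 1004 and 483 of them by at least 2-fold. With quantile normalization 4061 lay above and 4400 below, 830 and 616 by at least 2-fold. Above the median signal these were 2280 and 2654, and 242 and 157. His4r was at 1.01 (SE 0.11), NaPi-III at 0.73 and fend at 0.63.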

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

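The tests of a loss of CTCF or SuHw, of a set-wide offset, of a response already reached by the first knockdown, of low signal for each protein separately and of a second double-stranded RNA were chosen only after the result was seen. So were the additive model within the second set and the splitting of shared arrays.

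Each interaction below was singled out because the double differed from the sum of its singles, by limma's test of that difference. The BEAF+CP190 interaction crosses the sets, so there the set and the knockdowns cannot be told apart. The others set an effect within the second set against 1 within the first, and share the control arrays. An effect that differs by set would give the same there. So could control arrays that stand apart from every knockdown array, or a response to a second double-stranded RNA. The interactions called 8511 transcripts for BEAF+CP190, 4796 for BEAF+CTCF, 4551 for CTCF+CP190 and 4955 for SuHw+CP190. In BEAF+CP190 the named genes were His4r at 1.01, NaPi-III at 0.73, fend at 0.63, rdx at 0.47, Wdr24 at -0.46, sle at -0.41, Uba1 at -0.35, mio at -0.29 and LanA at -0.27 on the log2 scale. In BEAF+CTCF they were fend at 1.30, His4r at 0.54, NaPi-III at 0.31, kis at -0.62, sle at -0.35, alpha-Spec at -0.23 and Uba1 at -0.20. In CTCF+CP190 they were fend at 1.16, His4r at 0.57, Fatp1 at 0.37, kis at -0.54 and sle at -0.42. In SuHw+CP190 they were fend at 1.43, Fatp1 at 0.51, His4r at 0.45, sle at -0.48, Wdr24 at -0.36 and kis at -0.31. Single arrays ended some of these calls, and other arrays ended some of them too: without BEAF+CP190 replicate 1 rdx was at 0.41, and without CP190 replicate 1 mio was at -0.22 in BEAF+CP190, Fatp1 at 0.32 in CTCF+CP190 and Wdr24 at -0.32 in SuHw+CP190. Without BEAF+CTCF replicate 1 alpha-Spec was at -0.23 and Uba1 at -0.18, and without SuHw+CP190 replicate 2 kis was at -0.26. With only the groups compared in the fit, His4r (0.45), Wdr24 (-0.36) and kis (-0.31) in SuHw+CP190 and alpha-Spec (-0.23) and Uba1 (-0.20) in BEAF+CTCF were not called.

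The arrays divided into the first and second set, with a median absolute difference of 0.202 on the log2 scale between the means of the sets. Unequal intensity distributions of the deposited values are argued against, since quantile normalization of the 18 arrays left 0.993 of that difference. These distributions were already nearly alike, with upper quartiles of 11.753 to 11.765 in the first set and 11.722 to 11.735 in the second. A difference that arose before or during RMA was therefore not tested. Loss of CTCF or SuHw, targeted only in the second set, is argued against as the whole cause by the BEAF+CP190 arrays, which have neither knockdown and correlated with first-set BEAF and CP190 arrays at a mean of 0.9866 and with every other second-set array at 0.9912 or above. A set-wide offset stays open: the BEAF+CP190 interaction correlated at 0.357 with the other second-set groups minus control, between the bounds set for and against it, and the BEAF+CTCF, CTCF+CP190 and SuHw+CP190 interactions, in which an offset cancels, at -0.487, -0.459 and -0.476, but control enters both quantities with opposite signs. With first-set BEAF and CP190 in place of control it was 0.776 and the others -0.0844, -0.0613 and -0.12, and those arrays are shared too, so set and knockdown cannot be told apart there.

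BEAF and CP190 against control resembled each other in the first set and much less their own effects in the second. Noise of the 2 shared control arrays is argued against, since the covariance was 17.8 times the highest simulated. Control arrays that stand apart from every knockdown array may contribute, because the BEAF minus CP190 difference, which needs no control, correlated between the sets at 0.59. A shared biological response to losing any insulator protein, already reached by the first knockdown, would give the same. It cannot be told apart from control arrays that stand apart. The BEAF minus CP190 difference also removes what both second-set doubles share, such as a response to a second double-stranded RNA. That difference therefore cannot point to the control arrays alone. BEAF and CTCF against control correlated at 0.541, beside 0.498 for unchanged groups sharing the control arrays. The covariance was 0.122 beside a simulated 0.00507, and with the control arrays split the correlation was 0.516. These values cross the sets, so they cannot decide. Transcripts near the low end of the signal are argued against for CP190, whose effect correlated between the sets at 0.163 and 0.125 above the median signal, and stay open for BEAF, at 0.343, between the bounds set for and against.

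Within the second set, adding BEAF to CTCF and adding CP190 to SuHw changed transcripts alike, with a correlation of 0.435 and no shared array. Targets shared by BEAF and CP190 stay open: of the 1670 transcripts called the same way, 398 were called that way by both proteins in the first set against 213.5 from the shares of all transcripts, a ratio of 1.86 that lies between the bounds set for and against. A response to a second double-stranded RNA, whatever its target, could give the same correlation and cannot be told apart from it, because the design holds no control with 2 of them.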

How the results depend on the processing

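The additive model, the fit of arrays of the same set, the 1.5-fold gap, the splitting of shared arrays and all alternatives for transcripts set apart were chosen after the data were seen. With the fit of arrays of the same set, all 5 counts stayed within 1.5 times their value, as did 19 of 20 with only the groups compared. The exception was SuHw+CP190 against SuHw, at 1831. Quantile normalization moved 1 of 34 results, the correlation of CP190 against control with CP190 on SuHw, to 0.161. It turned the balance of higher and lower calls to 4249 and 4370 in SuHw+CP190 against CP190 and to 3968 and 3814 in BEAF+CTCF against BEAF, besides the comparisons named with the results. The labels do not say that a replicate number pairs samples, and the deviations of same-numbered arrays correlated at -0.20 to 0.45 over 36 pairs of groups (median 0.028, 10 pairs over 0.1). The replicate block moved none of the 20 counts by over 1.5 times, with 6972 for BEAF against control, and ended the call of 1 named gene, Fatp1 in CP190 against control (-0.19). Only transcripts above the median signal, fewer by construction, gave 4310 calls for BEAF against control, 3660 for CP190, 5543 for CTCF, 5867 for SuHw, 5666 for BEAF+CP190, 5617 for BEAF+CTCF, 5340 for CTCF+CP190 and 5485 for SuHw+CP190. Against singles they gave 5286 for BEAF+CP190 over BEAF and 5406 over CP190, 4826 for BEAF+CTCF over BEAF and 2323 over CTCF, 5063 for CTCF+CP190 over CP190, and 2994 for SuHw+CP190 over SuHw and 5417 over CP190. Their interactions numbered 4934 for BEAF+CP190, 2948 for BEAF+CTCF, 2999 for CTCF+CP190 and 3175 for SuHw+CP190. Among them the correlation of BEAF against control with BEAF on CTCF was 0.343, of CP190 on CTCF with CP190 on SuHw 0.792, of BEAF minus CP190 between the sets 0.676, of CTCF with SuHw 0.914 and of BEAF with CTCF against control 0.502. The cause of these shifts was not tested. Splitting the 2 shared arrays between the comparisons, which leaves each with fewer, gave 0.742 for BEAF with CP190 against control, 0.529 for BEAF with CP190 on CTCF, 0.855 for CTCF with SuHw and 0.516 for BEAF with CTCF against control. Leaving out single arrays gave 4316 to 6121 for BEAF against control, 2016 to 2099 for BEAF+CTCF against CTCF, 2325 to 3124 for CTCF+CP190 against CTCF, and 3130 to 5095 for SuHw+CP190 against SuHw. The lowest came without BEAF replicate 1, CTCF replicate 2, CTCF+CP190 replicate 1 and SuHw+CP190 replicate 2. For transcripts set apart by CP190 it gave 18 without replicate 2 and 20 without replicate 1. A gap of 1.5-fold gave 34 for BEAF, 56 for CP190 and 79 for SuHw. The additive model within the second set called 1446 for CTCF, 820 for SuHw, 5268 for BEAF+CP190, 2537 for BEAF+CTCF, 3563 for CTCF+CP190 and 2702 for SuHw+CP190. Of 51 named gene differences from control it kept 5 calls, ended 19 and turned the sign of 27. The 19 kept their sign, with mio at -0.16 to -0.32 in all 6 groups, SuUR at -0.15 to -0.19 in the 4 doubles, His4r at 0.25 for CTCF and 0.26 for SuHw, HDAC3 at 0.10 for CTCF and 0.14 for BEAF+CTCF and Wdr24 at -0.14. Smaller were Fatp1 for SuHw at -0.035 and alpha-Spec at 0.0057 for CTCF, 0.012 for BEAF+CP190 and 0.064 for CTCF+CP190. Turned were kis, at -0.087 for CTCF, -0.21 for SuHw, -0.20 for BEAF+CP190, -0.17 for BEAF+CTCF, -0.20 for CTCF+CP190 and -0.32 for SuHw+CP190, and in the same order fend, at 0.28, 0.15, 0.85, 0.96, 0.45 and 0.32. For sle it gave -0.092, -0.079, -0.22, -0.14 and -0.26 without SuHw+CP190, and for Fatp1 0.11 for CTCF, 0.30 for BEAF+CP190, 0.16 for BEAF+CTCF, 0.36 for CTCF+CP190 and 0.21 for SuHw+CP190. NaPi-III was at -0.20 for CTCF and -0.051 for SuHw, rdx at -0.046 for SuHw, and alpha-Spec at -0.040 for BEAF+CTCF and -0.054 for SuHw+CP190. By its construction this model leaves out control and assumes that knockdown effects add. Its level without CTCF or SuHw knockdown comes from the BEAF+CP190 arrays alone. The cause of these differences was not tested. Over the other alternatives, 67 of 103 named gene changes kept their call in each, and none turned. The gene lists, the targeted genes and the neighbouring genes were not run, with their alternatives. With no background measure, how far dim transcripts limit the counts was not measured.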

Other observations

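The count of transcripts set apart and its test by dividing whole groups were chosen only after the result was seen.

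Within the second set, SuHw set apart 46 transcripts, CTCF 15, CP190 13 and BEAF 11. With the replicates of each of the 6 groups kept together, the splits number 15 for SuHw and BEAF and 10 for CTCF and CP190, too few for a share under 0.05. The real split included, 1 split gave as many transcripts for SuHw (highest other 11), 1 for CTCF (highest other 13), 2 for CP190 (highest other 15) and 2 for BEAF (highest other 46). Each of these highest others is the split by another targeted protein. Splits that part replicates were not used, because replicates lie so close that such splits can hardly set a transcript apart.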
